A study of Caenorhabditis elegans with 12 samples.

How the data were processed

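Gene expression was measured in young adult Caenorhabditis elegans with the Affymetrix C. elegans Genome Array, in which short probes grouped into probe sets report the transcript level of a gene. The animals were fed bacteria that carried either an empty RNAi vector or a vector against sams-1, and grew with or without 30 mM choline. That made 4 groups of 3 arrays, 12 arrays in all. Per the labels' protocols, worms grew from hatching on agar with ampicillin, tetracycline and 6 mM IPTG, which induces the double-stranded RNA, and were collected when most had become young adults. The same protocols name total RNA from Tri-reagent, a column clean-up and biotinylated cDNA made with the Affymetrix WT PLUS kit.

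The deposited table holds 1 intensity per probe set and array on a linear scale, from 15.6 to 39457. Per the submitters' processing notes, the authors made these intensity values with RMA, which corrects the background, equalises the distributions between arrays and summarises the probes of a probe set. The RMA version and the annotation are not given in the sources used here. RMA pulls the arrays to nearly the same distribution, so a change of most transcripts in 1 direction would be partly removed. It also compresses changes of dim probe sets. The median intensity per array lay between 122.8 and 143.1, and the number of arrays per group, 3, limits the precision. All columns of the table belonged to a sample of the series. The design written beforehand assumed log2 values; the table turned out to be linear, and log2 was taken here before any test.

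Of 22625 probe sets, 77 were the manufacturer's controls, 20766 named 1 gene, 887 named several and 972 had no gene name in the platform annotation used here. Symbols were updated by gene identifier with a current RefSeq gene table (assembly WBcel235), which matched 20701 of the probe sets with 1 gene. Each gene was represented by its brightest probe set over all 12 arrays, which gave 17118 genes, of which 2981 had more than 1 probe set. Probe sets with several genes or none were kept out of the tests of genes. That leaves out sams-3, which shares its probe set with another gene. Probe sets of closely related genes can cross-hybridise, and the values of vit-4 and vit-5 come from probe sets marked as having probes in common with other sequences, so they are uncertain as to which vit gene they report.

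Replicates carry the letters A, B and C in the labels, which do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical. A linear model with 1 mean per group was fitted to each gene over all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (8 residual degrees of freedom, 10.18 after moderation). The 5 comparisons were sams-1 RNAi against empty vector without choline, choline in sams-1 RNAi animals, choline in empty vector animals, sams-1 RNAi against empty vector with choline, and the interaction, which is the difference between the knockdown changes with and without choline. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene in the text is limma's, SE is the moderated standard error of the log2 change, and SD is the spread of the 3 arrays of a group.

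Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists within each comparison, 180 tests in all. A further list, of genes encoded in mitochondrial DNA, had no member among the genes tested. Camera with the correlation estimated per list, and fry, were run beside it. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone.

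The genes named were fixed by rule: sams-1; the 8 largest changes each way among called genes whose 2 groups did not overlap (5 each way for choline in empty vector and for the knockdown with choline, and no overlap condition for the interaction); 14 preset genes of SAM, phosphatidylcholine and fat metabolism, immunity and stress; and up to 4 members of each list with the smallest p. Where a gene outside this rule is named, the text says so. These rules, the lists, the tests of genes and lists and the alternatives, apart from 2 added fits, were fixed before the data were examined. The tests of explanations for the C arrays, the germline genes and the infection genes, and the groupings within replicate letters, were chosen after results were seen.

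Whether the replicate letters pair the groups was checked from the correlation, across genes, of the arrays' deviations from their group means. For empty vector with and without choline the 3 correlations were 0.82, 0.85 and 0.90. For the choline-fed pair of vector and sams-1 RNAi they were 0.79, 0.85 and 0.89. All lay above the bound of 0.1 set for pairing. Values with the letter as a block are therefore given beside these 2 comparisons where they change a call or a count. A and B arrays of unlike letter were nearly as close. Empty vector A and choline-fed empty vector B correlated at 0.756, and choline-fed empty vector A and choline-fed sams-1 RNAi B at 0.788. The check thus shows that the C arrays shift together, and says little on whether A and B pair. For the pairs with the sams-1 RNAi group without choline at least 1 letter lay below that bound (-0.02, 0.44 and 0.18 for empty vector), and there the letters were not taken as pairs.

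The pipeline was tested on simulated data with known changes. For the knockdown without choline, 28% of 100 genes changed by a log2 of 0.5 and 79% of 100 genes changed by a log2 of 1 were recovered over 17118 genes, with 2 false calls among 109. For the interaction these shares were 7% and 60%, with 3 false calls among 70. Camera called a list shifted by a log2 of 0.4 and none of 36 unshifted lists (its adjusted p for the shifted list was 2.4e-37). The simulated noise was independent between genes and between arrays. The false calls counted here therefore do not cover genes of a list that vary together or arrays that shift together.

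The alternatives were the letter as a block, a fit of the groups compared alone, median centring, a second quantile normalization, removal of the genes below the 25th percentile of mean level (log2 5.635, which left 12838 genes), all probe sets, the mean of a gene's probe sets, a variance trend with robust moderation, array weights, a minimum change of 2-fold and the omission of each array in turn. A fit without all C arrays, and a block in a fit of only the 6 arrays compared, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.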

Results

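The series asked how expression changes when the S-adenosylmethionine synthetase gene sams-1 is knocked down, and how far dietary choline undoes it. Its enzyme makes S-adenosylmethionine, the methyl donor used by pmt-1 and pmt-2 to build phosphocholine, and choline enters phosphatidylcholine synthesis past those steps. Transcript levels were measured on 12 arrays, 3 each of empty vector, empty vector with choline, sams-1 RNAi and sams-1 RNAi with choline. Log2 changes are given with their SE from 3 arrays per group.

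The targeted gene sams-1 (C49F5.1) was reduced in all 6 arrays labelled sams-1 RNAi. Its log2 level was 12.94 ± 0.02 (SD, n = 3) in empty vector and 12.67 ± 0.30 (SD, n = 3) with choline, against 9.45 ± 0.15 (SD, n = 3) in sams-1 RNAi and 9.13 ± 0.62 (SD, n = 3) in sams-1 RNAi with choline. Without choline sams-1 fell (log2 change -3.48 ± 0.26, limma adjusted p = 6.2e-05), and with choline 11.6-fold (-3.53 ± 0.26, adjusted p = 0.0013). By 2 other sams-1 probe sets the changes were -3.64 and -1.22 without choline and -3.45 and -1.5 with it, so the size of the knockdown differed severalfold by probe set. The knockdown was not called as different between the diets (interaction -0.05 ± 0.37, adjusted p = 0.94).

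**Figure D1:**
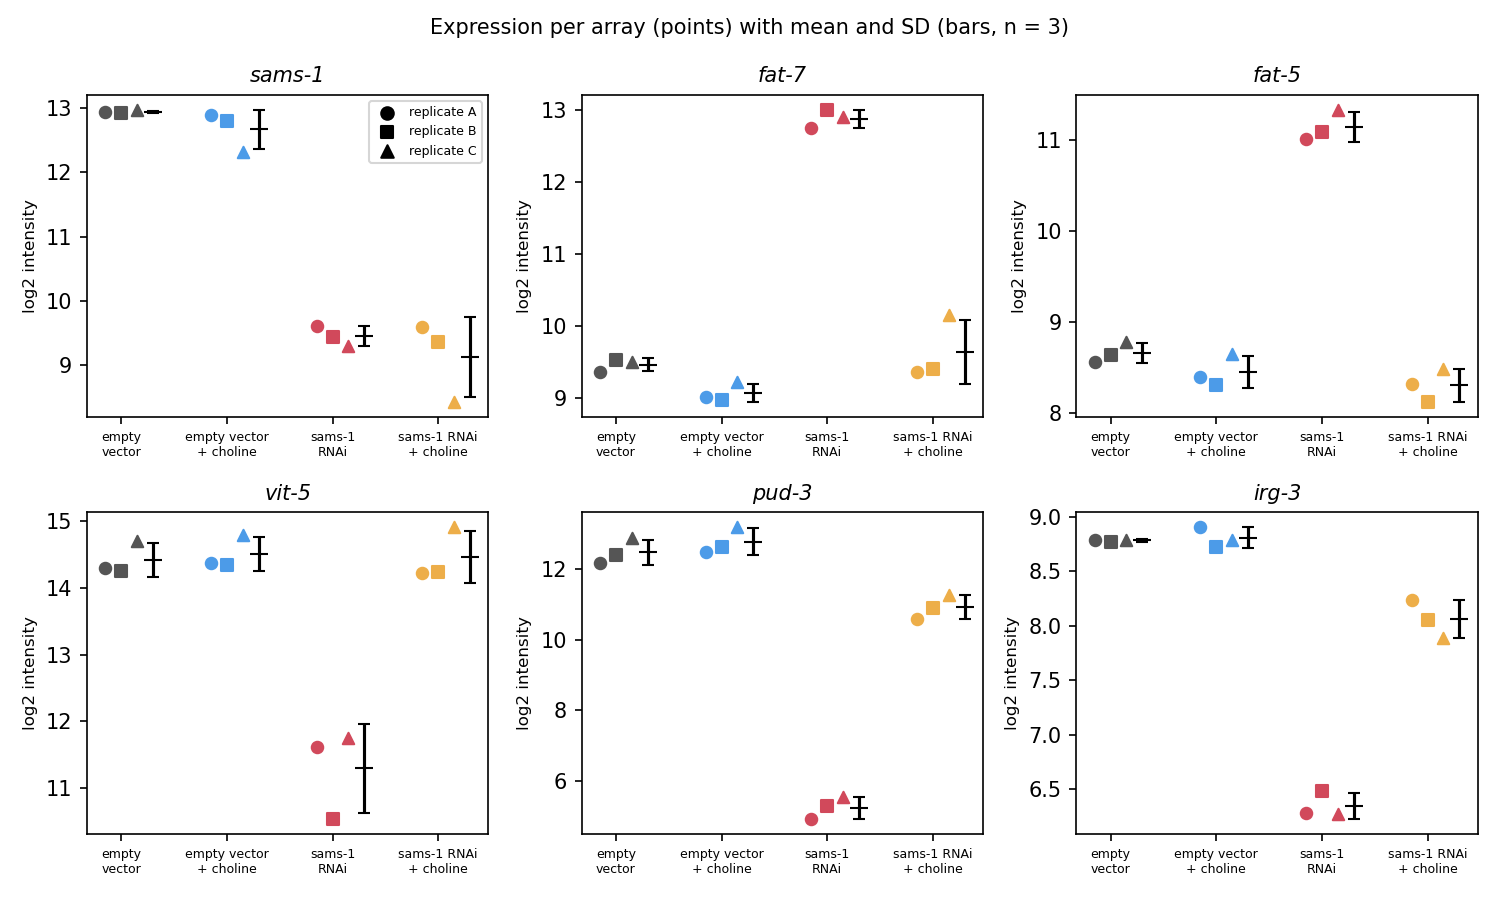
Log2 intensity of 6 genes in each of the 12 arrays; point shape gives the replicate letter, and bars give the mean and SD of the 3 arrays of a group. Sams-1 was low in all 6 knockdown arrays, while fat-7, fat-5 and vit-5 returned to near the empty vector level with choline and irg-3 and pud-3 stayed below it.

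Arrays fell into sets that the groups explained only in part. The sams-1 RNAi arrays without choline lay apart from all others, at -35.9 to -51.7 on the first principal component, which held 59.1% of the variance. The C arrays of the other 3 groups lay together at the opposite end, at 46.9 to 48.9, and the 6 A and B arrays of those groups lay between -6.4 and 0.8. Across genes, those A and B arrays correlated with each other at 0.996 to 0.999 and with the C arrays at 0.971 to 0.978. The difference between the 3′ and 5′ probe sets of the GAPDH control gene, a sign of RNA integrity, was a log2 of 0.94 ± 0.08 in empty vector, 0.83 ± 0.14 with choline, 0.76 ± 0.13 in sams-1 RNAi and 1.03 ± 0.14 in sams-1 RNAi with choline (SD, n = 3). It was highest in the C array in the 3 groups other than sams-1 RNAi without choline. The same difference for the actin control was 1.07, 1.06 and 1.25 in the C arrays of empty vector, choline-fed empty vector and choline-fed sams-1 RNAi, against 0.642 to 0.949 in their A and B arrays, and 0.645 in the sams-1 RNAi C array. For the ubiquitin control the C arrays of those 3 groups gave 2.975, 2.933 and 2.921. Their A and B arrays ran from 2.913 to 3.006, so this control showed no such rise in C.

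**Figure D2:**
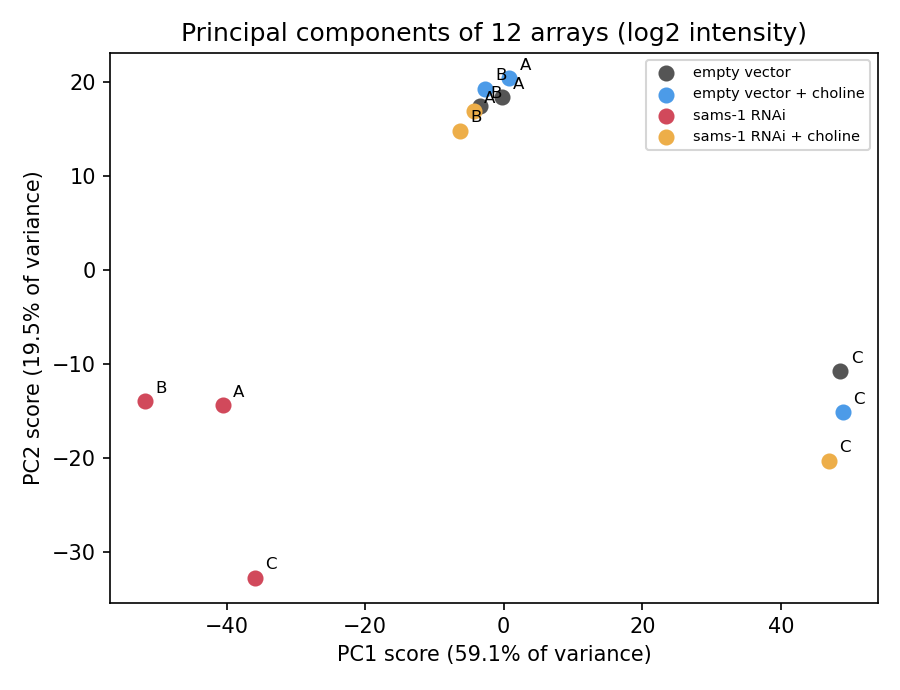
Scores of the 12 arrays on the principal components PC1 (59.1% of the variance) and PC2 (19.5%) of the log2 intensities of 17118 genes; colour gives the group and the letter the replicate. The 3 sams-1 RNAi arrays without choline lie at negative PC1 scores and the C arrays of the other groups at 46.9 to 48.9.

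Knockdown of sams-1 without choline raised fatty acid desaturases and lowered yolk proteins and germline transcripts. The largest rises were in the ARF-family GTPase gene warf-1, 67.7-fold (6.08 ± 0.30, adjusted p = 3.1e-06), Y41C4A.32, 45-fold (5.49 ± 0.53), the C-type lectin clec-47, 24.7-fold (4.63 ± 0.44), and F22E5.6, 17.5-fold (4.13 ± 0.45). Y37H2A.14 (4.11 ± 0.31), the cytochrome P450 cyp-13A5 (4.07 ± 0.21), the beta-tubulin tbb-6 (3.97 ± 0.20) and the methionine sulfoxide reductase msra-1 (3.86 ± 0.31) also rose by over 10-fold. The largest falls were in pud-3, 150-fold (-7.23 ± 0.26, adjusted p = 4.6e-07), and pud-4, 88.4-fold (-6.47 ± 0.19). Pud-3 read a log2 of 4.92 to 5.54 in sams-1 RNAi without choline, below the 25th percentile of mean level (5.635). The size of its changes against these arrays is therefore uncertain. The yolk protein genes vit-1 (-3.68 ± 0.34) and vit-5 (-3.13 ± 0.31) fell, as did sysm-1, also known as T24B8.5, 8.01-fold, txt-4 7.18-fold and Y40H7A.10 7.16-fold. Sysm-1 read 6.00, 5.35 and 5.41 in the sams-1 RNAi arrays A, B and C without choline. The last 2 lie below that percentile, so the size of its fall is uncertain too. In total 3149 of 17118 genes were called by limma (18.4%), 1123 higher and 2026 lower, and 597 of them changed by at least 2-fold, with the opposite balance (355 higher, 242 lower). The planned replicate block gave 5479 and array weights 9682, and a fit of only the 6 arrays compared gave 1810. The count fell to 1863 without empty vector array C and to 2053 without sams-1 RNAi array B, and was 5422 over the A and B arrays alone, a fit added after seeing the data, which shared 2947 genes with the 3149.

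Lipid synthesis genes rose together with the knockdown. Among 37 members of the fatty acid and triglyceride synthesis list around the SREBP homologue sbp-1, 16 rose and 1 fell (20 and 4 adjusted over the list alone), with a median change of 0.39 (camera adjusted p = 1.2e-08, and adjusted p = 0.014 with an estimated correlation). The delta-9 desaturases fat-7, fat-5 and fat-6 rose 10.6-fold (3.41 ± 0.18), 5.58-fold (2.48 ± 0.13) and 2.07-fold (1.05 ± 0.13), the delta-12 desaturase fat-2 rose by 1.17 ± 0.09 and the triglyceride-forming acyltransferase dgat-2 by 1.74 ± 0.16. Transcript of sbp-1 itself gave 0.09 ± 0.09 (adjusted p = 0.56). Of 23 phosphatidylcholine and phospholipid synthesis genes, 9 rose and 2 fell (13 and 5 adjusted over the list alone). They included the acyltransferase acl-12 (2.09 ± 0.19), the choline kinase ckb-2 (1.46 ± 0.23), the lipin lpin-1 (0.92 ± 0.13), the methyltransferases pmt-1 (0.53 ± 0.11) and pmt-2 (0.51 ± 0.11) and the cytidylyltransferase pcyt-1 (0.84 ± 0.19). The phosphatidylserine synthase pssy-2 fell by 0.76 (SE 0.13). That list's median was 0.24 (camera adjusted p = 0.0082, adjusted p = 0.15 with an estimated correlation). The pcyt-1 call was lost when only the groups compared were fitted (adjusted p = 0.072, the highest of a range from 2e-06 over the alternatives).

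The methionine cycle and the vitamin B12 pathways moved in part. In the SAM cycle and folate list 7 of 21 genes rose and 4 fell (7 and 4 adjusted over the list alone), and the list was not called (median 0.10, camera adjusted p = 0.059). Methionine synthase metr-1 rose by 1.34 ± 0.09, mmaa-1, of the B12-dependent mutase pathway, by 0.74 ± 0.09 and the ABC transporter pmp-5 by 1.64 ± 0.21. The paralogue sams-4 gave -0.05 ± 0.13 (adjusted p = 0.84). Of 21 propionate breakdown and B12 response genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.0042, adjusted p = 0.15 with an estimated correlation). They included acdh-1, an acyl-CoA dehydrogenase of propionate breakdown (0.78 ± 0.16, adjusted p = 0.0087), and the methionine synthase reductase mtrr-1 (0.90 ± 0.12). Fatty acid breakdown and fasting genes went both ways, with 8 of 40 higher and 6 lower (8 and 8 adjusted over the list alone; median 0.10, camera adjusted p = 0.14). In that list the lysosomal lipid carrier lbp-8 rose by 2.01 ± 0.18 and the hormone-sensitive lipase hosl-1 by 0.70 ± 0.07. The lysosomal lipase lipl-2 fell by 2.54 (SE 0.28), and the fasting gene acs-2 gave 0.84 ± 0.56 (adjusted p = 0.37).

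Immune genes split. Of 63 infection and p38 response genes, 19 rose and 17 fell (22 and 17 adjusted over the list alone; median 0.21, camera adjusted p = 0.075). The aspartyl protease asp-12 rose by 3.03 ± 0.11, whereas irg-3 (-2.44 ± 0.10), asp-14 (-2.08 ± 0.14), hpo-15 (-1.53 ± 0.12) and the p38 target sysm-1 fell. Irg-5 fell as well (-1.33 ± 0.32, adjusted p = 0.017), a call lost without empty vector array A (adjusted p = 0.053), sams-1 RNAi array A (0.051) or sams-1 RNAi array B (0.053), in a range of 1.1e-06 to 0.053 over all alternatives. Immune signalling components rose in 10 of 30 cases and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.4e-06, adjusted p = 0.075 with an estimated correlation). The Tribbles kinase nipi-3 rose by 1.64 ± 0.13, the MAP kinase phosphatase vhp-1 by 1.59 ± 0.20 and the receptor fshr-1 by 0.55 ± 0.09. The ERK kinase mpk-1 fell by 0.73 (SE 0.11). Of 71 lysozyme and antimicrobial peptide genes 11 rose and 5 fell (12 and 5 adjusted over the list alone; median 0.08, camera adjusted p = 0.0054, adjusted p = 0.15 with an estimated correlation), among them lys-6 and nlp-31, which rose, and spp-4 (-1.47 ± 0.17). Of 26 intracellular pathogen response genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), including pals-6 (1.55 ± 0.17) and skr-3 (1.45 ± 0.22). That list's median of 0.04 was -0.02 after median centring (camera adjusted p = 0.018, adjusted p = 0.24 with an estimated correlation). Among 220 C-type lectins 17 rose and 12 fell (16 and 10 adjusted over the list alone), led by clec-47, clec-72 (1.83 ± 0.14) and clec-17 (1.67 ± 0.14). The lectins' median was -0.05, their mean 0.01 and the direction of the test upward (camera adjusted p = 0.93).

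Detoxification, receptor, F-box and unfolded protein response genes were called more often upward than downward. Of 73 cytochrome P450 genes 9 rose and 5 fell (10 and 5 adjusted over the list alone), with cyp-33C8 at 2.80 ± 0.16 and cyp-13A4 at 1.90 ± 0.16 (median 0.04, -0.02 after median centring; camera adjusted p = 0.059). Of 109 glutathione and glucuronosyl transferases 16 rose and 14 fell (18 and 14 adjusted over the list alone), with ugt-16 at 2.68 ± 0.24 and ugt-19 at 2.28 ± 0.18. Their median was -0.02, their mean 0.09 and the test upward (camera adjusted p = 0.36). Nuclear hormone receptors rose in 41 of 255 cases and fell in 3 (41 and 2 adjusted over the list alone), nhr-232 by 1.35 ± 0.17, with a median of 0.04 that was -0.02 after median centring (camera adjusted p = 0.00012, adjusted p = 0.24 with an estimated correlation). Among 413 F-box and MATH-BTB genes 36 rose and 26 fell (32 and 22 adjusted over the list alone), fbxc-58 by 3.14 ± 0.34 (median -0.04, mean 0.02, test p adjusted to 0.76 by camera). Of 31 unfolded protein response genes of the endoplasmic reticulum 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 1.2e-06, adjusted p = 0.17 with an estimated correlation). They included the transcription factors xbp-1 (0.73 ± 0.15) and atf-6 (0.42 ± 0.09) and the chaperone enpl-1 (0.76 ± 0.16). The BiP chaperone hsp-4 rose by 0.90 ± 0.22 (adjusted p = 0.017), a call lost without empty vector array C (adjusted p = 0.071) or sams-1 RNAi array B (0.053), over a range of 5.7e-06 to 0.071 in all alternatives.

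Most proteasome subunits and 12 of 31 genes of the methyltransferase list fell. Whether these falls are separate from that of the germline genes, given below, was not tested. Most other stress and turnover lists had few calls or calls both ways. In the autophagy and lysosome list 6 of 27 genes rose and 1 fell (6 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.035, adjusted p = 0.42 with an estimated correlation), with the autophagy receptor sqst-1 up by 2.27 ± 0.14 and the cathepsin asp-4 by 0.87 ± 0.13. That list's call ended without empty vector array B (adjusted p = 0.083) or sams-1 RNAi array B (0.053). Heat shock genes were called in 3 cases higher and 2 lower of 18 (4 and 4 adjusted over the list alone), hsp-17 by 2.26 ± 0.39, with a median of -0.04 (0.01 after quantile normalization) and a mean of 0.32 (camera adjusted p = 0.69). The mitochondrial stress list had 1 of 16 genes higher and 1 lower (camera adjusted p = 0.8). The SKN-1 oxidative stress list had 2 of 25 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.49), gst-12 falling by 0.68 (SE 0.10). Of 23 DAF-16 target and longevity genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.14), fat-5 among the first and the metallothionein mtl-2 (-1.18 ± 0.24) among the second. Proteasome subunits fell in 25 of 33 cases and rose in 0 (28 and 0 adjusted over the list alone), by a median of -0.37, with rpn-7 at -0.61 ± 0.08 and rpt-1 at -0.50 ± 0.08 (camera adjusted p = 9.8e-11, adjusted p = 0.21 with an estimated correlation). Cytosolic ribosomal proteins had 2 of 75 genes lower, rpl-11.1 (-0.39 ± 0.07) and rpl-23A.2 (-0.35 ± 0.07), and a median of -0.06 (camera adjusted p = 0.036, adjusted p = 0.71 with an estimated correlation). The ribosomal call ended without empty vector array B (0.064) or C (0.073), choline-fed empty vector array C (0.053), or sams-1 RNAi array A (0.061) or C (0.13). The histone and protein methyltransferase list also names demethylases and complex subunits, so not all its members use S-adenosylmethionine. Its genes fell in 12 of 31 cases and rose in 0 (19 and 1 adjusted over the list alone), with prmt-1 at -0.67 ± 0.08 and set-32 at -0.71 ± 0.12 (median -0.40, camera adjusted p = 1.8e-05, adjusted p = 0.4 with an estimated correlation). Core histones rose in 8 of 29 cases and fell in 1 (9 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.004, adjusted p = 0.4 with an estimated correlation), his-4 by 1.42 ± 0.21. His-74 fell by 0.97 (SE 0.11). The nicotinic signalling and choline transport list had 3 of 27 genes higher and 1 lower, with a median of 0.06 that was -0.00 after median centring (camera adjusted p = 0.099).

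Germline and yolk transcripts fell with the knockdown. Of 51 germline and oocyte genes 42 fell and 0 rose (49 and 0 adjusted over the list alone), by a median of -0.84 (camera adjusted p = 4e-19, adjusted p = 0.21 with an estimated correlation). The median was -0.79 in the A and B arrays and -0.92 in the C arrays. The P granule genes deps-1 (-1.19 ± 0.12), pgl-1 (-0.86 ± 0.10) and pgl-3 (-0.89 ± 0.11) and the oocyte maturation gene oma-1 (-1.09 ± 0.16) were among them. All 5 yolk protein genes measured fell, among them vit-4 by -2.78 ± 0.29 and vit-6 by -1.83 ± 0.33, with a median of -2.78 (camera adjusted p = 8.2e-06, adjusted p = 0.21 with an estimated correlation; 5 adjusted over the list alone). Sperm genes had 0 of 47 called by limma over all genes or adjusted over the list alone, with a median of 0.13 that was -0.16 in the A and B arrays and 0.70 in the C arrays (camera adjusted p = 0.05, not under the threshold, and adjusted p = 0.81 with an estimated correlation). Of 31 early embryo genes 2 rose and 2 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.53). Cuticle and moulting genes had 8 of 164 lower and 0 higher, col-184 by -0.99 ± 0.20, though 0 passed adjusted over the list alone and their median was 0.20 (camera adjusted p = 0.0034 upward, adjusted p = 0.71 with an estimated correlation). Camera's call of that list ended without empty vector array C (0.18) or sams-1 RNAi array A (0.092).

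Somatic tissue lists moved upward in part. Neuronal genes rose in 10 of 44 cases and fell in 2 (10 and 2 adjusted over the list alone; median 0.20, camera adjusted p = 5.9e-05, adjusted p = 0.15 with an estimated correlation), with the synaptic genes unc-13 (1.11 ± 0.16) and unc-18 (0.76 ± 0.11) and the neuropeptide gene flp-9 (1.12 ± 0.16). Body wall muscle genes rose in 7 of 34 cases and fell in 0 (7 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 8.2e-06, adjusted p = 0.35 with an estimated correlation), with the troponin tnt-3 at 0.91 ± 0.13 and the actinin atn-1 at 0.60 ± 0.12. Intestinal genes rose in 11 of 34 cases and fell in 7, the yolk genes among the latter (13 and 7 adjusted over the list alone). Their median was 0.26, their mean -0.02 and the test upward (camera adjusted p = 0.042, adjusted p = 0.15 with an estimated correlation), and the P-glycoprotein pgp-1 rose by 2.74 ± 0.27. The intestinal call ended without empty vector array C (0.093) or sams-1 RNAi array A (0.058), B (0.088) or C (0.067). Pharynx genes had 0 of 23 called by limma (median 0.08, camera adjusted p = 0.35). Hypodermal genes had 1 of 23, grd-3, lower (median 0.20, camera adjusted p = 0.092), and excretory canal and coelomocyte genes 1 of 14, aqp-2, higher (camera adjusted p = 0.69). The aqp-2 call ended without empty vector array C (0.06).

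**Figure D3:**
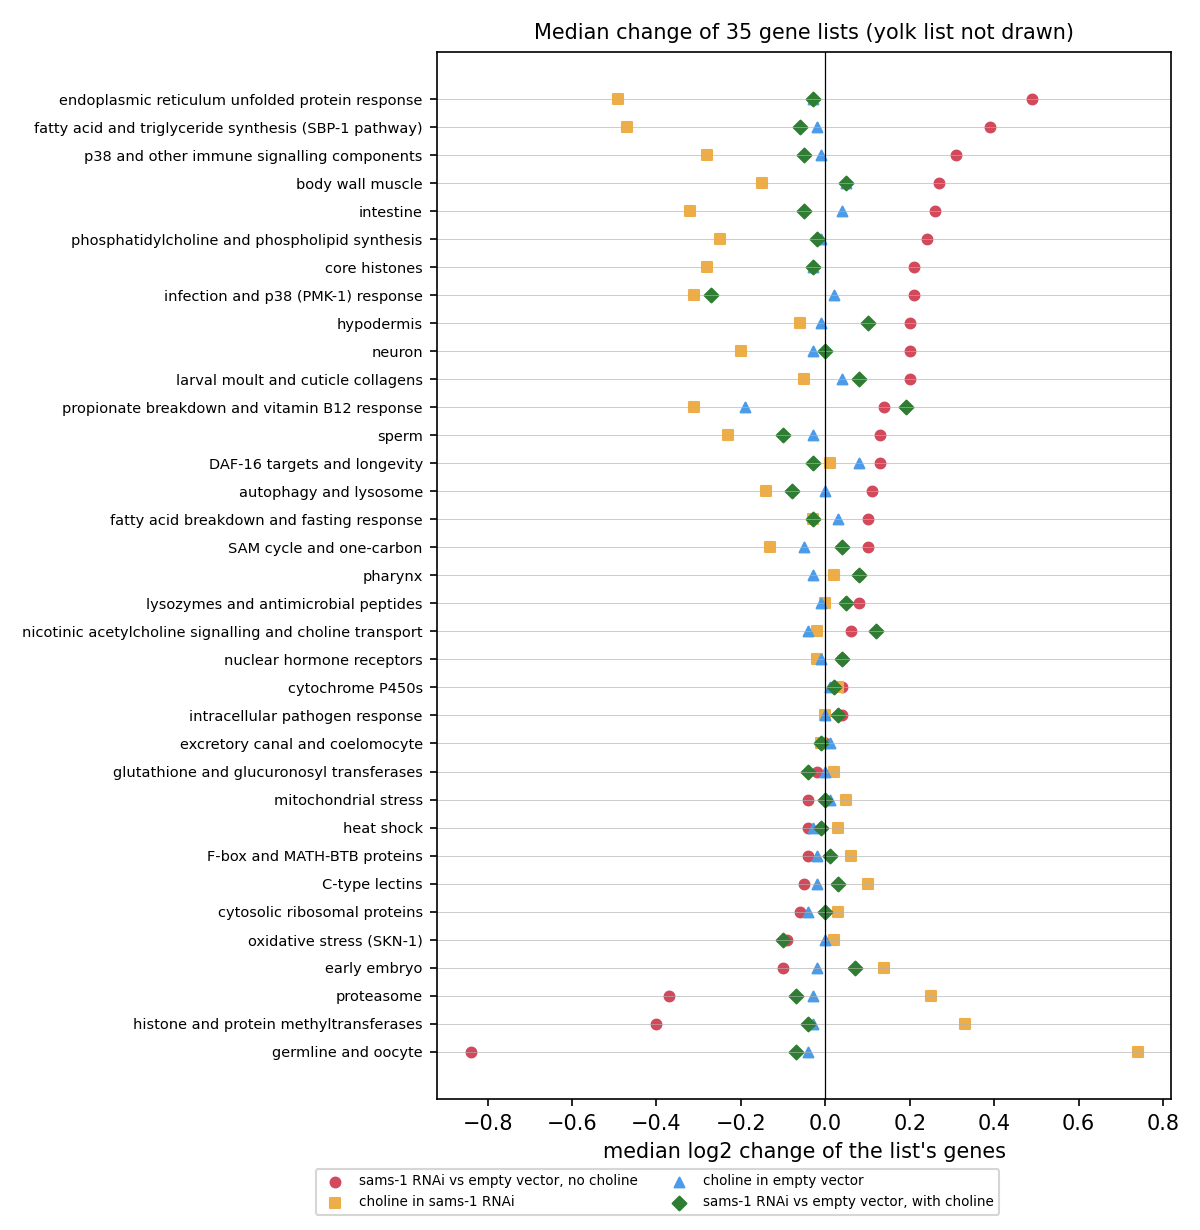
Median log2 change of the members of 35 gene lists (yolk proteins, at -2.78 and 2.74 in the first comparisons, are not drawn) in 4 comparisons, with no error drawn; positive values are higher in the group named first or with choline. Germline genes, at -0.84 with the knockdown and 0.74 with choline in sams-1 RNAi, and SBP-1 pathway genes, at 0.39 and -0.47, lie on opposite sides, while medians near 0, such as 0.04 for the P450 and nuclear receptor lists with the knockdown (-0.02 after median centring, which moved the median of all genes from -0.03 to -0.09), give no direction.

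Choline given to sams-1 RNAi animals, the comparison in the series title, moved the same gene groups in the other direction. Pud-3 rose 50.9-fold (5.67 ± 0.26, adjusted p = 1.9e-06), pud-4 27.1-fold (4.76 ± 0.19), and the yolk genes vit-1, vit-5 and vit-4 rose by 3.65 ± 0.34, 3.17 ± 0.31 and 2.74 ± 0.29. Y40H7A.10 (2.42 ± 0.38) and txt-4 (2.33 ± 0.26) rose as well. T13F3.6 rose by 2.49 ± 0.56 (adjusted p = 0.017), a call lost without sams-1 RNAi array B (0.073) or its choline-fed array C (0.063), over a range of 9.5e-07 to 0.073 in all alternatives. Warf-1 fell 97.3-fold (-6.60 ± 0.30, adjusted p = 1.9e-06), Y41C4A.32 69.7-fold, Y37H2A.14 22-fold, tbb-6 21.4-fold, cyp-13A5 18.1-fold, C08E8.4 18-fold, F22E5.6 15.9-fold and clec-47 15.1-fold. Limma called 2135 genes (12.5%), 1146 higher and 989 lower, and 465 of these changed by at least 2-fold, with the opposite balance (102 higher, 363 lower). The replicate block gave 4673, array weights 10151 and a fit of only the 6 arrays compared 823. The count was 1192 without sams-1 RNAi array B, 1218 without the choline-fed sams-1 RNAi array A and 1204 without its array C, and 4391 over the A and B arrays alone, of which 2000 were shared with the 2135.

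Lipid synthesis genes fell with choline in these animals. Of the 37 genes of the SBP-1 pathway 18 fell and 0 rose (19 and 1 adjusted over the list alone), by a median of -0.47 (camera adjusted p = 4.8e-12, adjusted p = 0.0042 with an estimated correlation). Fat-7 fell 9.42-fold (-3.24 ± 0.18), fat-5 7.15-fold (-2.84 ± 0.13), fat-6 2.55-fold (-1.35 ± 0.13), and fat-2 by 1.12 (SE 0.09). Phosphatidylcholine genes fell in 8 of 23 cases and rose in 1 (12 and 3 adjusted over the list alone; median -0.25, camera adjusted p = 0.0015, adjusted p = 0.091 with an estimated correlation). They included acl-12 at -1.95 ± 0.19, ckb-2 at -1.53 ± 0.23, pcyt-1 at -1.19 ± 0.19 and pmt-1 at -0.71 ± 0.11. Sbp-1 (-0.19 ± 0.09), pmt-2 (-0.30 ± 0.11), sams-4 (0.09 ± 0.13) and sams-1 (-0.32 ± 0.26) were not called. The SAM cycle list had 2 of 21 genes higher and 6 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.2 with an estimated correlation), metr-1 among those that fell. The propionate and B12 list had 1 of 21 higher and 6 lower (1 and 7 adjusted over the list alone; median -0.31, camera adjusted p = 0.008, adjusted p = 0.15 with an estimated correlation), with the receptor nhr-114 at -1.75 ± 0.24. Acdh-1 (-0.31 ± 0.16, adjusted p = 0.27) and acs-2 (-0.38 ± 0.56, adjusted p = 0.68) were not called.

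Some immune and stress lists fell as well, and others did not. The heat shock, mitochondrial stress and SKN-1 lists had medians of 0.03, 0.05 and 0.02. Immune signalling components fell in 13 of 30 cases and rose in 1 (15 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 3.9e-09, adjusted p = 0.02 with an estimated correlation), with nipi-3 at -1.72 ± 0.13, vhp-1 at -1.60 ± 0.20 and the MAP kinase pmk-3 at -0.95 ± 0.14. Infection response genes fell in 21 of 63 cases and rose in 6 (22 and 11 adjusted over the list alone; median -0.31, camera adjusted p = 6.4e-05, adjusted p = 0.089 with an estimated correlation). Asp-12 fell by 2.95 (SE 0.11) and C17H12.8 by 1.54 (SE 0.12). Irg-3 rose by 1.72 ± 0.10, whereas irg-5 (0.04 ± 0.32, adjusted p = 0.95) and sysm-1 (1.07 ± 0.51, adjusted p = 0.21) were not called. Unfolded protein response genes fell in 8 of 31 cases and rose in 0 (10 and 0 adjusted over the list alone; median -0.49, camera adjusted p = 1.6e-07, adjusted p = 0.15 with an estimated correlation), among them xbp-1 (-0.80 ± 0.15) and hsp-4 (-1.01 ± 0.22, adjusted p = 0.014). Nuclear hormone receptors fell in 38 of 255 cases and rose in 0 (40 and 1 adjusted over the list alone), though their median of -0.02 was 0.07 after median centring, which moved that of all genes from 0.05 to 0.14 (camera adjusted p = 0.00015, adjusted p = 0.25 with an estimated correlation). Autophagy and lysosome genes fell in 7 of 27 cases and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.25 with an estimated correlation), sqst-1 by 2.32 (SE 0.14).

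Germline, oocyte and yolk transcripts rose with choline in sams-1 RNAi animals, and sperm transcripts did not. Germline and oocyte genes rose in 35 of 51 cases and fell in 0 (49 and 1 adjusted over the list alone; median 0.74, camera adjusted p = 4.4e-18, adjusted p = 0.21 with an estimated correlation). Deps-1 rose, as did pgl-3 at 0.73 ± 0.11 and gld-1 at 0.72 ± 0.12. Their median was 0.73 in the A and B arrays and 0.79 in the C arrays. All 5 yolk genes rose (5 adjusted over the list alone; median 2.74, camera adjusted p = 2e-06, adjusted p = 0.18 with an estimated correlation). Proteasome genes rose in 7 of 33 cases and fell in 0 (16 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 4.6e-07, adjusted p = 0.28 with an estimated correlation). Genes of the methyltransferase list rose in 4 of 31 cases (11 and 0 adjusted over the list alone; median 0.33, camera adjusted p = 0.00022, adjusted p = 0.49 with an estimated correlation). Core histones fell in 6 of 29 cases and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 8.5e-05, adjusted p = 0.25 with an estimated correlation). Neuronal genes fell in 12 of 44 and rose in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.089 with an estimated correlation). Sperm genes had 0 of 47 called by limma over all genes or adjusted over the list alone. Their median of -0.23 was 0.09 in the A and B arrays and -0.96 in the C arrays (camera adjusted p = 0.0014, adjusted p = 0.79 with an estimated correlation). The call of that list ended without sams-1 RNAi array C (adjusted p = 0.061) or the choline-fed sams-1 RNAi array C (0.85). Of the 36 lists, camera called 20 here and 19 in the knockdown without choline, and 2 and 1 of these held with an estimated correlation.

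No gene was called at the threshold for choline in empty vector animals. Fat-7 gave -0.39 ± 0.18, acdh-1 -0.47 ± 0.16, sysm-1 -0.46 ± 0.51, pmt-1 0.21 ± 0.11, fat-5 -0.21 ± 0.13 and hsp-4 -0.06 ± 0.22, each with an adjusted p of 1. Limma called 0 genes, and 99 passed an unadjusted p under 0.05, where 856 would do so by chance alone. The shift of the C arrays, alike in both groups (r = 0.90 across genes), counts as residual spread in this fit and lowers its power. The 0 calls therefore do not show that choline had no effect. The other limma fits with all 12 arrays gave 0 as well, except that array weights called 14 genes (5 higher, 9 lower). The fit of the A and B arrays alone called 7 higher and 7 lower. With the replicate letter as a block the count stayed 0 over 12 arrays, and was 6 in a fit of the 6 arrays compared, which was chosen after seeing the data. Without the block those 6 arrays gave 0 by limma, with 175 genes at an unadjusted p under 0.05. The 6 genes called with the block are named for that call, whether or not the naming rule gives them. The P450 cyp-34A9 (0.99 ± 0.05, adjusted p = 0.011) and the alcohol dehydrogenase adh-1 (0.75 ± 0.06, adjusted p = 0.034) were higher. Nhr-114 (-0.70 ± 0.05, adjusted p = 0.025), grl-23 (-1.02 ± 0.07), T05E12.6 (-0.98 ± 0.06) and nspe-1 (-0.62 ± 0.05) were lower. Nhr-114, a receptor of the B12 response, had adjusted p-values from 0.025 to 1 over the alternatives.

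Gene lists moved little with choline in empty vector. Camera called 7 of 36 lists, none of which held with an estimated correlation, and fry called 0. The propionate and B12 list had the largest median, -0.19 (camera adjusted p = 0.0019, adjusted p = 0.28 with an estimated correlation), a call that ended without empty vector array A (adjusted p = 0.083). Muscle genes (median 0.05), cuticle genes (0.04), ribosomal protein genes (-0.04), DAF-16 targets (0.08), P450 genes (0.01) and infection genes (0.02) were the others, at adjusted p = 0.87 for the infection genes and adjusted p = 0.91 for the rest with an estimated correlation. Each of these calls ended without at least 1 array. Muscle ended without empty vector array C (0.47) or choline-fed arrays A (0.14) or B (0.73), ribosomal proteins without empty vector array C (0.085) or choline-fed array B (0.092), and cuticle without choline-fed arrays A (0.98) or B (0.42). Without empty vector array C the cuticle median turned negative, at -0.09 (0.014). DAF-16 targets ended without empty vector array A (0.13) or B (0.23), choline-fed array C (0.11), sams-1 RNAi array A (0.063) or its choline-fed arrays B (0.05) or C (0.051). P450 genes ended without empty vector arrays A (0.71) or B (0.7), choline-fed array C (0.81) or choline-fed sams-1 RNAi arrays B (0.05) or C (0.051). Infection genes ended without empty vector array C (0.98), choline-fed arrays A (0.49) or B (0.42), or choline-fed sams-1 RNAi arrays B (0.056) or C (0.072). SBP-1 pathway genes (median -0.02, camera adjusted p = 0.86) and germline genes (median -0.04, camera adjusted p = 0.42) were not called. With the replicate block over 12 arrays, the fasting list was called too (median 0.03, camera adjusted p = 0.04).

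Sams-1 RNAi with choline, set against empty vector with choline, left few called differences in the fit without a block. Apart from sams-1, the largest falls were in pud-4, 4.41-fold (-2.14 ± 0.19, adjusted p = 0.0033), pud-3, 3.62-fold (-1.86 ± 0.26), dod-22, 3.05-fold (-1.61 ± 0.22), and the C-type lectin clec-67, 2.25-fold (-1.17 ± 0.15). The largest rises were in msra-1, 5.78-fold (2.53 ± 0.31), the lysozyme lys-4, 4.27-fold (2.09 ± 0.29), pmp-5, 3.98-fold (1.99 ± 0.21), srh-237, 3.79-fold (1.92 ± 0.21), and T05E12.6, 3.41-fold (1.77 ± 0.18). Fat-7 (0.57 ± 0.18), fat-5 (-0.15 ± 0.13), fat-6 (-0.36 ± 0.13), pmt-1 (-0.39 ± 0.11) and hsp-4 (-0.05 ± 0.22) were not called, each with an adjusted p of 1. Limma called 20 genes, 8 higher and 12 lower (10 higher and 8 lower after quantile normalization), and 13 changed by at least 2-fold (7 higher, 6 lower). The count was 12 without empty vector array A, 13 without empty vector array B, 5 without the choline-fed empty vector array A or B, 13 without sams-1 RNAi array B, and 12, 2 and 10 without the choline-fed sams-1 RNAi arrays A, B and C. Sams-1 and pud-4 were the 2 genes called without array B of the choline-fed sams-1 RNAi group. Without it pmp-5, T05E12.6, srh-237 and msra-1 ended at an adjusted p of 0.053, dod-22, clec-67 and lys-4 at 0.093 and pud-3 at 0.15. Without the choline-fed empty vector array A, srh-237 (0.079), msra-1 (0.092), pud-3 (0.092), dod-22 (0.13), clec-67 (0.16) and lys-4 (0.18) ended, and without its array B, srh-237 (0.06), msra-1 (0.07), pud-3, dod-22 and clec-67 (0.13 each) and lys-4 (0.17). Without its array C, msra-1 and clec-67 (0.061 each), pud-3 (0.088) and dod-22 (0.099) ended, and without choline-fed sams-1 RNAi array C, pud-3 (0.051), clec-67 (0.059), lys-4 (0.086) and dod-22 (0.087). Pud-3, dod-22 and lys-4 also ended without the choline-fed sams-1 RNAi array A (0.14, 0.1 and 0.079), empty vector array A (0.05, 0.052 and 0.051), empty vector array B (0.06, 0.057 and 0.052) or sams-1 RNAi array B (0.062, 0.056 and 0.052), and lys-4 without sams-1 RNAi array A (0.055). With the replicate block 35 genes were called over 12 arrays (15 higher, 20 lower) and 207 in the 6 arrays compared (64 higher, 143 lower). A planned fit of those 6 arrays without the block called 0 genes by limma (smallest adjusted p = 0.067, 821 at an unadjusted p under 0.05), which ended all 20 calls. Over the A and B arrays alone 49 genes were higher and 55 lower, all 20 among them.

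Infection response genes stood out in this comparison. Of 63 measured, 6 fell and 1 rose (17 and 3 adjusted over the list alone), by a median of -0.27 (camera adjusted p = 3.5e-14, adjusted p = 0.0076 with an estimated correlation). The falls included K08D8.5 (-0.99 ± 0.10), asp-14 (-1.14 ± 0.14), irg-3 (-0.75 ± 0.10), dod-22, clec-67 and the lysozyme lys-1 (-0.63 ± 0.09), and the rise was in lys-4. Without the choline-fed empty vector arrays A, B and C, asp-14 ended at 0.092, 0.075 and 0.055, irg-3 at 0.16, 0.096 and 0.088 and lys-1 at 0.22, 0.2 and 0.073, and K08D8.5 without A (0.066) or B (0.06). Without choline-fed sams-1 RNAi arrays B and C, asp-14 ended at 0.067 and 0.051, irg-3 at 0.13 and 0.071 and lys-1 at 0.13 and 0.086, and K08D8.5 without B (0.053). Irg-3 and lys-1 ended without empty vector array A (0.052 and 0.067) or B (0.057 and 0.076), and lys-1 without empty vector array C (0.051), sams-1 RNAi array B (0.067) or choline-fed sams-1 RNAi array A (0.072). The list held 7 of the 20 called genes. Irg-5 was lower by a similar amount as without choline (-1.39 ± 0.32, adjusted p = 0.44, and adjusted p = 0.0016 with the block in 6 arrays, in a range of 1e-04 to 1 over all alternatives). Sysm-1 gave -1.47 ± 0.51 (adjusted p = 1), with -2.06 over the A and B arrays and -0.30 in the C arrays. The propionate and B12 list rose in median by 0.19, with 2 of 21 genes higher and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.00054, adjusted p = 0.13 with an estimated correlation) and acdh-1 at 0.94 ± 0.16 (adjusted p = 0.11, and 0.042 with the block over 12 arrays, in a range of 6.3e-05 to 0.89). Germline genes had a median of -0.07 (camera adjusted p = 0.018, adjusted p = 0.84 with an estimated correlation), a call that ended without choline-fed empty vector array C (0.62) or choline-fed sams-1 RNAi arrays A (0.14) or B (0.5). SBP-1 genes had a median of -0.06 (camera adjusted p = 0.021, adjusted p = 0.29 with an estimated correlation), which ended without choline-fed empty vector arrays B (0.051) or C (0.09) or choline-fed sams-1 RNAi array C (0.21). Proteasome genes had a median of -0.07 (camera adjusted p = 1e-05, adjusted p = 0.72 with an estimated correlation). Limma called 0 members of these 3 lists. Camera called 11 lists, 1 of which, the infection list, held with an estimated correlation. With the block over 12 arrays the autophagy (-0.08, adjusted p = 0.048), muscle (0.05, adjusted p = 0.016) and hypodermis (0.10, adjusted p = 0.0076) lists were called as well, and the early embryo list was not (adjusted p = 0.1).

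Over the genes called in the knockdown, the change with choline was a small part of that without (slope 0.112, given below). The interaction was called with opposite sign for 522 of these 3149 genes. The interaction was largest upward for pud-3 (5.37 ± 0.36), pud-4 (4.32 ± 0.26) and vit-1 (3.50 ± 0.48) and downward for warf-1 (-6.68 ± 0.42), Y41C4A.32 (-6.32 ± 0.75) and tbb-6 (-4.28 ± 0.28). For the desaturases it was -2.84 ± 0.26 for fat-7, -2.63 ± 0.18 for fat-5 and -1.41 ± 0.18 for fat-6 (adjusted p = 0.00054, 1e-04 and 0.0039). Limma called 527 genes (3.08%), 230 higher and 297 lower, and 226 of at least 2-fold (35 higher, 191 lower). With the planned replicate block the count was 2690 and the balance turned (1617 higher, 1073 lower), as it did with array weights (3992 higher, 2838 lower). The count was 222, 295 and 273 without empty vector arrays A, B and C, 218 and 197 without the choline-fed empty vector arrays A and B, 886 and 291 without sams-1 RNAi arrays A and B, and 243, 247 and 320 without its choline-fed arrays A, B and C. Over the A and B arrays it was 2447 (1434 higher, 1013 lower), of which 509 were shared. Of the 36 lists camera called 22, and 2 held with an estimated correlation: the SBP-1 pathway (median -0.40, adjusted p = 0.0032 with an estimated correlation) and the immune signalling components (-0.33, adjusted p = 0.019 with an estimated correlation).

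Among the 3149 genes of the knockdown, 522 (16.6%) had a called interaction of opposite sign. With choline in sams-1 RNAi 1962 (62.3%) were called in the opposite direction, and 18 (0.572%) were still called in the same direction in the knockdown with choline. The 18 come from the fit without a block, where 521 genes passed an unadjusted p under 0.05 against 856 by chance. The block in 6 arrays called 207 genes, so the 18 do not count all genes that stayed changed. Of the 1123 genes that rose, 855 fell with choline (76.1%; 64.9 for independent lists), and of the 2026 that fell, 1107 rose (54.6%; 136 for independent lists). Both comparisons share the 3 sams-1 RNAi arrays, which are too few to split, so part of the excess may come from them. Across genes, which are not independent replicates, the changes correlated at -0.955 with a covariance of -0.222. Simulations with no effects and the same shared group gave -0.494 and -0.0228. They were built from the variance of each gene. Shifts that many genes share within an array may thus make chance values larger in size than these. The slope of the knockdown change with choline on that without, which share no arrays, was 0.112, with 0.125, 0.110 and 0.0895 for the letters A, B and C (SD 0.0179, n = 3), 0.0253 for genes that rose and 0.208 for genes that fell. In 20 simulations with equal effects on both diets the slope was 0.929 and 2363 genes were still called with choline. The slope was 0.147 and 0.0588 without the choline-fed empty vector arrays B and C, 0.0758 and 0.131 without sams-1 RNAi arrays A and C, and 0.0811 and 0.159 without its choline-fed arrays B and C. The number with a called opposite interaction was 219, 293 and 271 without empty vector arrays A, B and C, 216 and 195 without the choline-fed arrays A and B, 867 and 289 without sams-1 RNAi arrays A and B, and 241, 245 and 313 without its choline-fed arrays A, B and C.

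**Figure D4:**
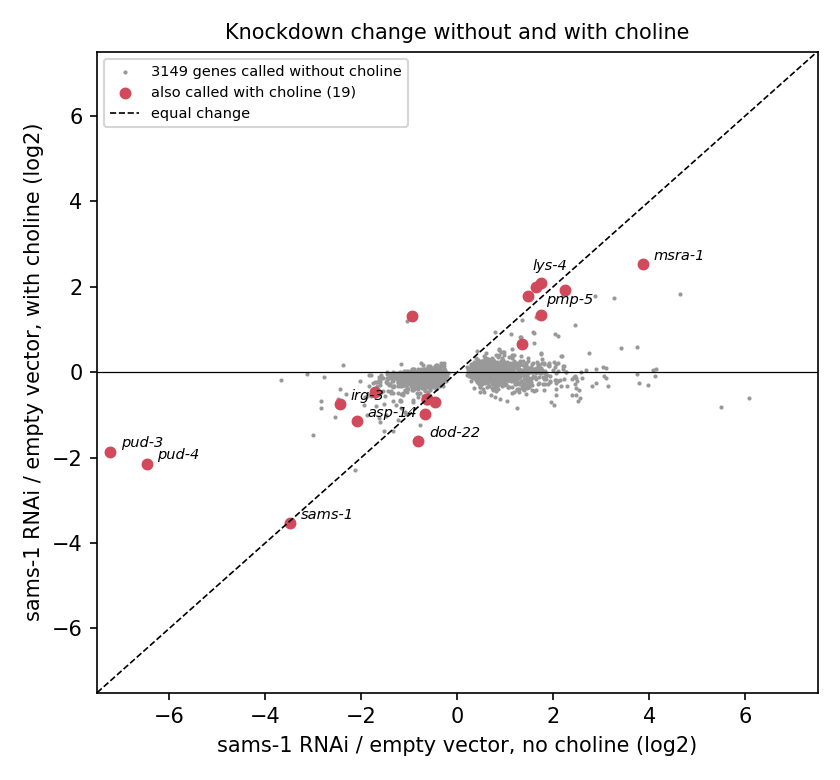
Log2 change with sams-1 RNAi without choline (horizontal) and with choline (vertical) of the 3149 genes called without choline; red marks the 19 that were also called with choline, 18 in the same direction, and the dashed line marks equal change. Most points lie near 0 on the vertical axis, while sams-1 lies on the dashed line at -3.48 and -3.53.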

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

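The groupings that kept 1 array of each replicate letter per group were chosen only after the counts under free groupings were seen.

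Among called genes the interaction was largest in size for warf-1 and Y41C4A.32, and it was also called for pud, yolk and lipid genes. The interaction, in log2 with its SE, was 5.37 (0.36) for pud-3, 4.32 (0.26) for pud-4, 3.50 (0.48) for vit-1, 3.09 (0.44) for vit-5, 2.67 (0.40) for vit-4, 2.25 (0.18) for C09B8.4, 2.24 (0.33) for acdh-2 and 2.01 (0.37) for txt-4. In the other direction it was -6.68 (0.42) for warf-1, -6.32 (0.75) for Y41C4A.32, -4.28 (0.28) for tbb-6, -4.20 (0.44) for Y37H2A.14, -4.06 (0.63) for F22E5.6, -4.04 (0.54) for C08E8.4, -4.03 (0.29) for cyp-13A5 and -3.79 (0.71) for sdz-35. C09B8.4 fell with the knockdown without choline (-0.94) and was called higher with the knockdown on choline. The txt-4 call ended without choline-fed empty vector array A (adjusted p = 0.055) or B (0.06) or choline-fed sams-1 RNAi array A (0.053).

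Among the preset lipid genes the interaction was -2.84 (0.26) for fat-7, -2.63 (0.18) for fat-5, -1.41 (0.18) for fat-6, -1.24 (0.27) for pcyt-1 and -0.92 (0.16) for pmt-1. The pmt-1 call ended without choline-fed empty vector array B (adjusted p = 0.056). The pcyt-1 call ended without empty vector arrays A (0.1), B (0.088) or C (0.059), choline-fed empty vector arrays A (0.095), B (0.12) or C (0.054), sams-1 RNAi array B (0.063) or choline-fed sams-1 RNAi arrays A (0.095), B (0.08) or C (0.089). The median interaction was -0.40 for the SBP-1 lipid synthesis list and -0.33 for the immune signalling components. The sdz-35 call ended without empty vector array A (0.061), empty vector array B (0.055), empty vector array C (0.053), choline-fed empty vector array A (0.063), choline-fed empty vector array B (0.062), choline-fed sams-1 RNAi array A (0.06) or choline-fed sams-1 RNAi array B (0.058).

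Chance was not excluded for the 527 interaction genes by other groupings of the same 12 arrays. Of 100 groupings drawn, 5 gave as many genes, the real one included, and the highest other gave 3274. Of the 4 others, 3 kept the sams-1 RNAi arrays without choline together and 1 kept the C arrays of the other 3 groups together, and without either set kept together the highest was 13, so the large counts point to these 2 structures of the samples. For the 522 knockdown genes with a called interaction of opposite sign, the reduced genes, 3 of 100 groupings gave as many, and the highest other gave 3188.

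These groupings moved arrays freely between the replicate letters, although the C arrays of 3 of the 4 groups shift together. Of 100 groupings with 1 array of each letter per group, 3 gave as many interaction genes, the real one included, with 1043 in the highest other, and 2 gave as many reduced genes, with 1042 in the highest other. The 2 others with as many interaction genes kept the sams-1 RNAi arrays together, as did 2 with fewer, and without these arrays together the highest was 10. For the interaction genes the share was thus 0.05 or more in the planned free groupings and under 0.05 in these. For the reduced genes it was under 0.05 in both. The shares in both kinds of grouping rest largely on the distance of the sams-1 RNAi arrays from the rest.

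For the single comparisons there are 10 splits of 6 arrays, which cannot give a share under 0.05. Knockdown without choline gave 3149 genes against 0 in the highest other split, with 1 of 10 as large. Choline in sams-1 RNAi gave 2135 against 0, with 1 of 10, and the knockdown with choline 20 against 0, with 1 of 10. Choline in empty vector gave 0 by limma in the real split and in the highest other, 10 of 10, with 99 genes at an unadjusted p under 0.05 and 14 by array weights.

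Probe sets with no single gene name were tested apart. Of 1782, 66 were higher with the knockdown without choline and 150 lower. No gene is named for them here.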

How the results depend on the processing

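The fits without all C arrays and with a block in the 6 arrays compared were chosen after the data were seen, and the other alternatives before.

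Counts are given in the order knockdown without choline, choline in sams-1 RNAi, knockdown with choline, interaction, and reduced genes. Reduced genes are knockdown genes with a called interaction of opposite sign. The main fit gave 3149, 2135, 20, 527 and 522. The replicate block gave 5479, 4673, 35, 2690 and 2671, array weights 9682, 10151, 487, 6830 and 6061, and leaving out all C arrays 5422, 4391, 1.0e+02 (49 higher and 55 lower), 2447 and 2408. Array weights, whose estimation stopped before it converged, rested largely on sams-1 RNAi array B, at a weight of 36.1 against 0.193 and 0.174 for its A and C arrays. A minimum of 2-fold gave 597, 465, 13, 226 and 209. Fits of only the groups compared gave 1810, 823 and 0 for the first 3. Trend with robust moderation gave 340 for the interaction and 338 reduced, and quantile normalization gave 786 reduced. For choline in empty vector, 0 became 14 by array weights, 14 without all C arrays and 6 with the block in 6 arrays, where the knockdown with choline gave 207.

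Leaving out 1 array gave 1863 to 3561, 1192 to 2316, 2 to 24, 197 to 886 and 195 to 867, and a slope of 0.0588 to 0.159 against 0.112. The slope was 0.134 by array weights and 0.149 without all C arrays. Of 180 gene list tests, 79 calls became 6 with an estimated correlation and 47 by fry.

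No named gene with a call changed sign in any alternative. Without all C arrays the sperm list turned to 0.0935 for choline in sams-1 RNAi and 0.117 for the interaction, and the DAF-16 list to -0.0496 for choline in empty vector. Over fits without 1 array, list medians for choline in empty vector ran from -0.0936 to 0.207 for cuticle, -0.0247 to 0.167 for muscle, -0.0627 to 0.109 for P450 and -0.154 to 0.128 for DAF-16 genes. For the knockdown with choline they ran from -0.2 to 0.0728 for germline and -0.0806 to 0.253 for cuticle genes. The cause was not tested.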

Other observations

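The tests of the C arrays, the germline genes and the infection genes in this part were chosen only after their results were seen.

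Cuticle genes differed between the C arrays and the A and B arrays, in part in all 4 groups. In empty vector, choline-fed empty vector and choline-fed sams-1 RNAi, in that order, F15B9.8 was lower in C by a log2 of -3.30, -3.19 and -3.31 (-0.61 in sams-1 RNAi without choline). The collagens bli-1 (-3.03, -2.92 and -3.39), col-49 (-3.09, -3.17 and -2.94) and sqt-1 (-2.85, -2.78 and -3.01) and the gene dao-4 (-3.24, -2.96 and -3.15) were lower as well. In sams-1 RNAi without choline these 4 gave -2.23, -0.51, -1.14 and -0.94. Higher in C were the caveolin cav-1 (2.35, 2.28 and 2.57), the C-type lectin clec-223 (2.22, 2.35 and 2.20), dod-3 (2.34, 3.60 and 2.04) and the noncoding RNA tts-1 (1.87, 3.76 and 1.93), with 1.31, 2.33, -0.14 and 0.71 in sams-1 RNAi without choline. These genes were chosen after their values were seen, with 1 C array per group and no test.

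Infection genes differed in how far they returned on choline, within both the raised and the lowered set. Of the raised genes, asp-12 went from 3.03 with the knockdown to 0.11 with choline, irg-2 from 2.04 to -0.18, cnc-4 from 1.89 to -0.27, and hpo-6 from 2.02 to -0.78, cpr-3 from 1.25 to -0.83, C17H12.8 from 0.78 to -0.59 and lys-2 from 0.47 to -0.46. The last 4 were called lower on choline with the block in 6 arrays (adjusted p = 0.0056 to 0.018) and not over 12 arrays without one (0.24 to 1), and 13 of the 19 raised genes lay below 0, so the lower median of the list on choline comes in part from them. In contrast lys-4 went from 1.74 to 2.09, acdh-1 from 0.78 to 0.94 and lys-5 from 0.58 to 0.34. Among the lowered genes dod-22 went from -0.81 to -1.61, K08D8.5 from -0.68 to -0.99, irg-5 from -1.33 to -1.39, C32H11.4 from -1.53 to -1.37 and dod-24 from -1.62 to -1.17. Clec-86 went from -2.31 to -0.51, dod-23 from -1.93 to -0.58, irg-3 from -2.44 to -0.75, spp-1 from -0.79 to -0.27, clec-60 from -0.59 to -0.03 and ilys-5 from -0.71 to 0.17. A difference between the raised and the lowered set was not tested, and apart from the genes named by rule, these were chosen after their values were seen.

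Developmental stage is a candidate explanation for the position of the C arrays of 3 groups. If C samples were older, cuticle and sperm genes would be lower and yolk genes higher in C, and 9 of 9 list medians over the 3 groups lay that way, beyond 95% of random lists (sperm -0.66, -0.67 and -0.85, yolk 0.42, 0.44 and 0.69). This does not decide for C cultures at another developmental stage. The lists were picked after the shifts were seen, the C shifts of the 3 groups correlate at 0.89 to 0.90, so they are not separate results, and members of a list vary together. In sams-1 RNAi without choline cuticle (-0.30) and yolk (0.68) genes shifted that way in C too, and sperm genes (0.24) the other way. For hybridisation and washing of the C arrays, the added control probe sets would shift as much as the cuticle list, but the largest ratio of their shifts was 0.3. The median log2 of these control probe sets was itself 9.457 in empty vector array A and 9.011 in B. These 2 arrays lay further apart than the cuticle shift in that group (-0.35), so the ratio cannot exclude hybridisation or washing. The 3′ to 5′ difference of actin, a sign of RNA quality, moved with the same arrays (1.07, 1.06 and 1.25 in these C arrays, 0.645 in that of sams-1 RNAi). That of ubiquitin did not (2.975, 2.933 and 2.921 in these C arrays, 2.913 to 3.006 in their A and B arrays). RNA quality was not tested as a cause and stays open beside stage.

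Germline genes were lower with the knockdown by a median of -0.84, and the axis that separates the C arrays may account for a part of it. Over all genes the knockdown change correlated with that axis at -0.46. With the axis removed the median was -0.69 (bootstrap interval -0.76 to -0.57), and 50 of 51 members stayed below 0. The bootstrap resampled genes with the arrays and the axis held fixed, so its interval does not measure the spread between samples. A smaller share of germline RNA, in animals with fewer germ cells, would raise all other tissues alike. Medians were 0.35 for intestine without yolk genes, 0.27 for muscle, 0.20 for neuron, 0.20 for hypodermis and 0.08 for pharynx, and a permutation test gave p = 0.14 for a difference, which does not show that they were equal. Dissected germlines or counts of germ cells could separate fewer cells from lower transcript levels per cell. A difference in developmental stage between sams-1 RNAi and empty vector animals was not tested for the germline and yolk falls and stays open. Stage is also a candidate for the axis removed here.

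Infection genes that fell with the knockdown kept a median of 54.9% of the change on choline (17 genes), and an incomplete return shared by all lowered genes could not be told apart from a dependence on sams-1 beyond choline. The list drew attention because it was low on choline, which makes a comparison with random sets of lowered genes void. Taken in each letter apart, the share exceeded that of matched lowered genes by 42.4 points on average (95% interval 12.1 to 72.8, n = 3). This interval cannot decide the question, because it uses the same choline-fed arrays in which the list was seen to be low. The shares of all letters were also divided by the same knockdown change. In the C arrays another list kept more, the fasting genes at 73.7% against 51.6%. Over the A and B arrays alone the median change with choline was -0.93, against -0.99 over all arrays, so the C arrays alone did not make it. With choline irg-5 had an adjusted p of 0.44 over 12 arrays without a block and was called with the block in 6 arrays (0.0016). Sysm-1 was called in neither (1 and 0.091). The genes of the set are not independent. Other methyl acceptors were not measured, so the route from sams-1 to these genes is open.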
